A study of Homo sapiens with 6 samples.

How the data were processed

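RNA-seq gene counts of 6 libraries of Huh7 cells were used, 3 from cells with a control guide and 3 from cells with a guide against HNRNPA2B1. Per the labels' protocols, RNA was isolated with a column kit and libraries were made with a SMARTER mRNA kit from total RNA. The deposited table holds raw counts of reads per gene, made by the authors. The submitters' processing notes name the hg19 human genome build, with no role given. The aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here. A gene and an overlapping or antisense partner can therefore share reads, as can close paralogs and processed pseudogenes.

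The table has 25202 rows, 19974 with an Ensembl gene ID and 5228 for loci that the authors' pipeline added under names of its own. Of the Ensembl IDs, 19883 were found in a table of gene symbols. The added loci were kept in library sizes and in the test and have no symbol. All rows are named, and 3195 rows hold 0 counts in all libraries. Each of the 6 columns was matched to its sample by the name in that sample's description. Totals ran from 32517757 to 38870244 counts per library.

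Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr with default settings (16331 genes), and libraries were scaled by TMM. TMM factors were 0.955, 0.935 and 0.925 in control replicates 1, 2 and 3 and 1.08, 1.07 and 1.04 in knockout replicates 1, 2 and 3. The groups were compared by edgeR's quasi-likelihood test with group as the single term. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p below 0.05. A 2-fold change required an absolute log2 fold change of 1 or more. CPM values are TMM-scaled and were computed from the deposited counts, not by the authors. Errors are the SD over 3 libraries for CPM, and for log2 fold changes an SE derived from the fitted value and its F statistic. The biological coefficient of variation was 17.6%.

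The 38 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule named HNRNPA2B1, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of 3 or more whose knockout libraries lay outside the control range, and the 5 smallest remaining p-values. It also named up to 4 members with the smallest p of each list that passed and up to 2 of each other list with 3 or more called members. Some genes that the rule named are not reported here, and genes named outside it are said to be so. The lists cover hepatocyte, lipid, stress, interferon, RNA-processing, cell cycle, signalling, housekeeping, RNA quality and other cell type genes. Lists with at least 5 tested members were compared by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. An estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were alternatives. Each list's median was also placed among 10000 random lists matched on mean expression in 20 bins. A gene with no counts in a group is given as a bound against a floor of 3 counts over the group. Such bounds cover counting error only.

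The same code was tested on simulated data for this comparison, with 16331 genes drawn from the real means and spreads and 50 genes changed at each of 4 sizes. It recovered 24% of genes changed 1.5-fold, 66% at 2-fold, 88% at 4-fold and 94% at 8-fold, and 7 of its 143 calls were false. Replicates were compared for libraries deposited more than once. The chi-square per degree of freedom between libraries of a group was at least 9.47, far above sampling noise, so all 6 libraries were counted. That lowest value was between knockout replicates 1 and 2. The other knockout pairs had 31.2 and 31.3 and the control pairs 58.0 to 90.3, so the knockout libraries were closer to each other than the controls were.

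Other settings fixed beforehand were DESeq2's size factors, upper-quartile scaling, library size alone, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, an adjusted p below 0.01 and leaving out each library in turn. Leaving out the added loci, cyclic loess with limma-trend, and offsets for GC content and transcript length were added after seeing the data. GC content, transcript length and 3′ UTR sequence came from GENCODE release 29, whose genome build differs from hg19, so no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.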

Results

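RNA was sequenced from Huh7, an established human hepatoma cell line, in 2 groups of 3 libraries. The control group carried a non-targeting guide, and the other group carried a guide against HNRNPA2B1 and is labelled a knockout. HNRNPA2B1 encodes an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein (hnRNP) family with roles in splicing and RNA transport. The values were read counts per gene. Totals were 38870244, 32690070 and 32517757 counts in control replicates 1, 2 and 3 and 36809274, 32702480 and 34273448 in knockout replicates 1, 2 and 3. Of 25202 rows, 16331 had enough counts to be tested. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Nor do they say whether the knockout cells were a single clone or a pool.

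The first question was the level of the targeted gene in each library. HNRNPA2B1 (ENSG00000122566) had 40867, 32755 and 44149 counts in the controls and 8729, 8232 and 8364 counts in the knockout libraries. Its mean level was 1214 ± 221 CPM (SD, n = 3) in the controls and 229 ± 8.30 CPM (SD, n = 3) in the knockout, 5.29-fold lower. The log2 fold change was −2.40 ± 0.14 (SE), with an edgeR adjusted p of 2.28e-06. Each knockout library lay below each control library. The position of the guide is not given in the sources used here, and gene-level counts do not tell intact from edited transcript.

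**Figure D1:**
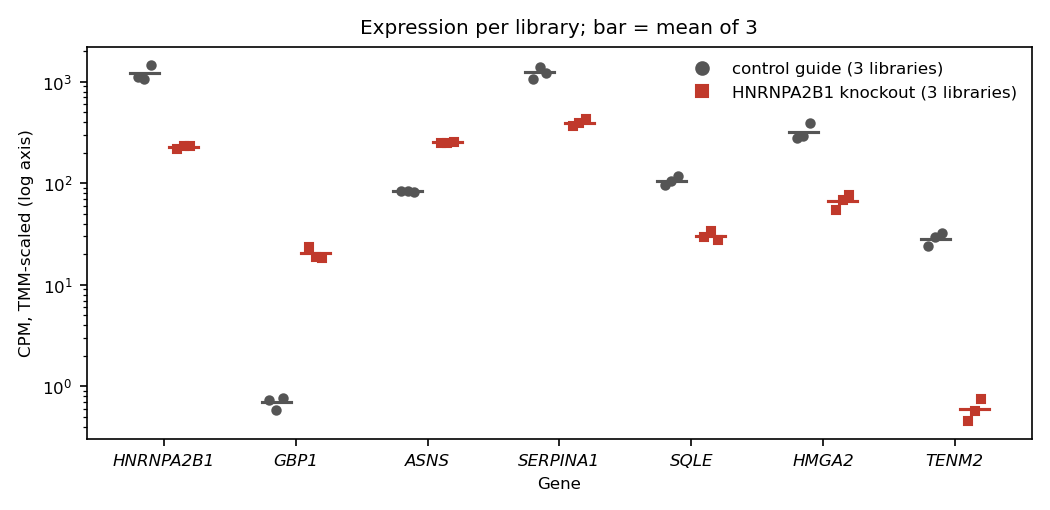
Level of 7 genes in each of the 6 libraries, in CPM after TMM scaling on a log axis. Circles are the 3 control libraries, squares the 3 knockout libraries, and bars the group means. HNRNPA2B1 had a mean of 1214 CPM in the controls and 229 CPM in the knockout, and for each gene shown the groups did not overlap. GBP1, HMGA2 and TENM2 were named by a rule that required this.

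The groups separated on the largest axis of variation between libraries. The first principal component of log2 CPM held 63.7% of the variance and split control from knockout. The second held 13.1% and set control replicate 3 apart, at −51.3 against 29.1 and 25.3 for control replicates 1 and 2. Across genes, which are not independent replicates, the correlation of log2 CPM was 0.974 to 0.977 between controls, 0.982 to 0.985 between knockout libraries and 0.943 to 0.954 between the groups. More genes had at least 1 count in the knockout libraries after thinning to equal total counts. They numbered 19420 ± 207 against 17998 ± 191 in the controls (SD, n = 3, exact permutation p = 0.1, 2-sided, the smallest this design allows). Mitochondrial transcripts took 2.01%, 3.06% and 4.70% of counts in control replicates 1, 2 and 3 and 2.15%, 2.78% and 2.51% in the knockout.

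The main comparison asked which genes differed between knockout and control cells. By edgeR's quasi-likelihood test at an adjusted p below 0.05, 3448 genes rose and 3100 fell, together 6548 or 40.1% of those tested. At least 2-fold, 1733 rose and 540 fell. The excess of rises was largest among genes of low abundance. Below a mean log2 CPM of 3, 1244 genes rose 2-fold and 202 fell. From 3 upward, 489 rose and 338 fell. The median log2 fold change was 0.67 over the 2188 genes with a mean log2 CPM below 0 and −0.21 over the 3879 genes at 6 or more. Loci without an Ensembl ID that the authors' pipeline had added made up 717 of the 3448 called rises and 117 of the 3100 called falls. The knockout libraries lay wholly above or below the controls for 54.3% of tested genes, against 10% by chance for 3 against 3.

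The share of rises among the called genes moved with the scaling. It was 52.7% with TMM, 49.9% with DESeq2's size factors, 64.4% with upper-quartile scaling and 72.1% with library size alone. Those last 2 scalings shifted the median log2 fold change of all genes from 0.05 to 0.16 and 0.24. Offsets for GC content and transcript length gave 40.2%, with a median of −0.06 over all genes. Cyclic loess with limma-trend gave 57.7% rises among the 2-fold calls in place of 76.2%. That setting changed the scaling and the test together and used log2 CPM with a prior count of 2, so the drop cannot be credited to the scaling alone. Log2 fold changes of rare genes were smaller there, 4.32 in place of 5.95 for MMP7 and 2.35 in place of 2.95 for IFIH1. A prior count by itself shrinks the log2 fold changes of genes with few counts, and its part in these drops was not measured.

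**Figure D2:**
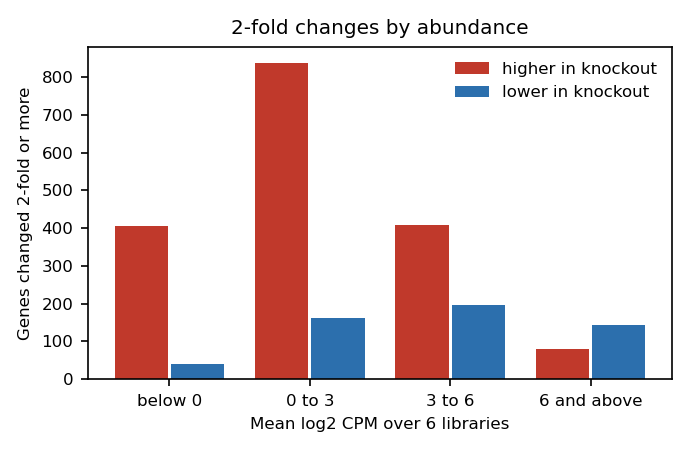
Number of genes changed at least 2-fold at an edgeR adjusted p below 0.05, by mean log2 CPM over the 6 libraries. Rises in the knockout outnumber falls in each class below 6, while 80 genes rose and 142 fell in the class at 6 and above.

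Among genes with a mean log2 CPM of at least 3, the 10 largest rises were 16-fold or more. KLHDC7B had the largest, from 0.350 ± 0.038 to 15.9 ± 0.636 CPM (SD, n = 3 each; log2 fold change 5.49 ± 0.21 SE, edgeR adjusted p = 3.46e-07; 4.88 with cyclic loess). OLR1, a receptor for oxidised low-density lipoprotein, rose from 1.51 ± 0.474 to 53.5 ± 4.19 CPM. GBP1, an interferon-inducible GTPase, had a log2 fold change of 4.87 ± 0.21 (SE). TFPI2, a serine protease inhibitor, rose by 4.61 ± 0.20 and the actin cross-linker FLNC by 4.15 ± 0.17 on the log2 scale. ANKRD1, an ankyrin-repeat cofactor, rose by 4.14 ± 0.15, the glucuronosyltransferase UGT2A3 by 4.08 ± 0.14, the lysyl oxidase LOXL2 by 4.02 ± 0.23 and NIBAN1 by 4.01 ± 0.22. Reads of GBP1 and UGT2A3 can be shared with related genes, so their values are uncertain to that extent. The 5 smallest remaining p-values belonged to genes that rose as well, the hexokinase-like HKDC1 (2.81 ± 0.13), the annexins ANXA1 (3.69 ± 0.17) and ANXA3 (2.41 ± 0.12), the laminin chain LAMA3 (2.81 ± 0.13) and UBE2L6 (2.85 ± 0.14), which conjugates the ubiquitin-like protein ISG15.

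The largest fall at the same abundance was that of TENM2, a teneurin cell-surface protein, from 28.5 ± 4.19 to 0.593 ± 0.152 CPM (SD, n = 3 each; log2 fold change −5.59 ± 0.22 SE, edgeR adjusted p = 3.46e-07). ATP2B2, a plasma membrane calcium pump, had a log2 fold change of −3.25 ± 0.21 (SE), from 104 ± 18.2 CPM in the controls (SD, n = 3). The G-protein subunits GNAZ and GNG4 had log2 fold changes of −2.95 ± 0.22 and −2.38 ± 0.16 (SE). The growth factor receptor PDGFRA changed by −2.61 ± 0.17, the hepatocyte asialoglycoprotein receptor ASGR1 by −2.60 ± 0.15 and the matrix protein SMOC1 by −2.38 ± 0.19. HMGA2, an architectural chromatin protein, fell from 323 ± 63.3 to 66.6 ± 11.3 CPM (SD, n = 3 each). HNRNPA2B1 itself was among these 10 genes. All 6 libraries showed the direction of each gene named in the last paragraph and in this one. For the 10 largest rises and 10 largest falls the naming rule required this, so it is no separate result.

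Next, 38 gene lists fixed before the data were examined were compared as groups. With camera at a preset correlation of 0.01, 4 of the 37 lists large enough to test shifted upward and 16 downward. That balance moved with the method: 7 lists went up and 8 down with cyclic loess, and 12 up and 13 down by fry, a rotation test. No list passed with an estimated correlation, where the lowest adjusted p was 0.0933, so each camera call below stands beside that p. Ranges over other settings are those of camera and leave out the estimated correlation and fry. Library size alone and cyclic loess brought the medians of many falling lists nearer 0: to −0.14 and −0.08 for SR splicing factors (−0.32), −0.09 and −0.01 for the unfolded protein response (−0.27), −0.06 and −0.05 for oxidative phosphorylation (−0.24), −0.06 and −0.08 for N6-methyladenosine genes (−0.24), −0.20 and −0.20 for heat shock (−0.38) and −0.23 and −0.22 for the hnRNP family (−0.42). With library size alone they were −0.16 for liver transcription factors, −0.33 for fatty acid synthesis and −0.24 for S phase. They were −0.27 for mitosis and −0.09 for ribosomal proteins. That scaling moves all genes alike and took the median of all genes from 0.05 to 0.24. Less that median, lists stayed in place, at −0.47 in both fits for the hnRNP family and −0.37 for SR splicing factors. Changes with library size alone given below hold the same common shift. Cyclic loess, with a median of −0.004 over all genes, did move these lists against other genes. Offsets for GC content and length moved medians the other way, to −0.41 for oxidative phosphorylation and −0.39 for N6-methyladenosine genes. The offsets also moved the median of all genes from 0.05 to −0.06, so such moves are not due to GC content and length alone. Counts of members refer to the edgeR test over all genes, followed by those adjusted over the list alone.

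**Figure D3:**
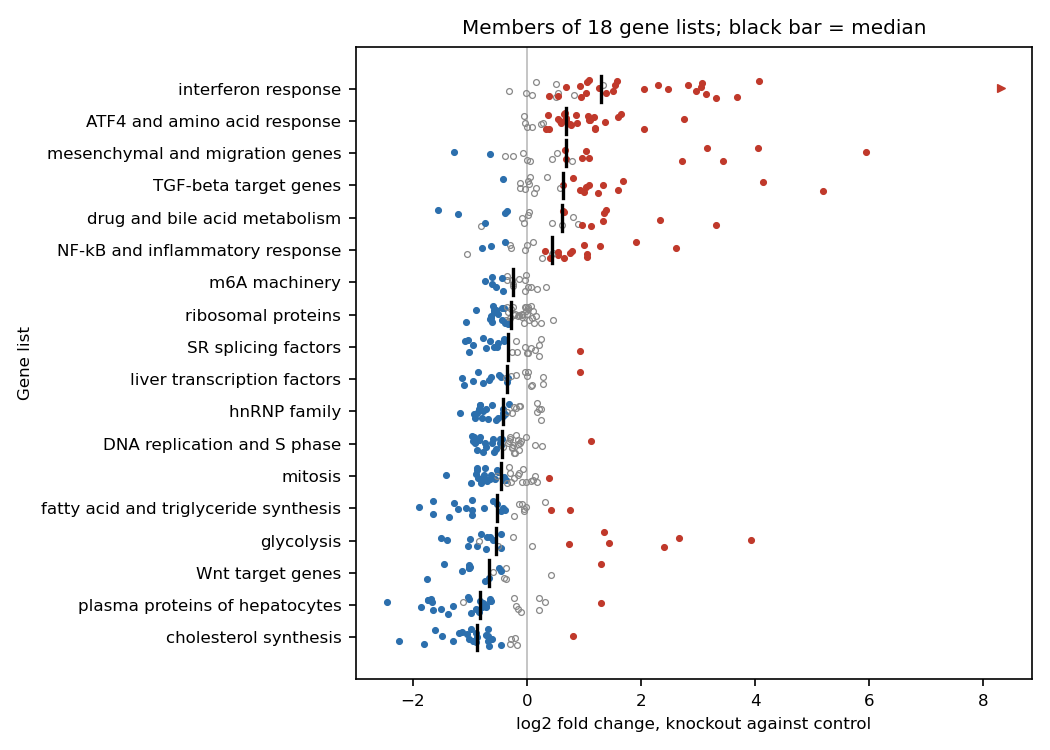
Log2 fold changes (knockout against control) of the members of 18 gene lists, a point per gene, filled where the edgeR adjusted p was below 0.05 and open where not, with the list median as a black bar. The triangle is BST2, drawn at its lower bound. The median was 1.30 for interferon response and −0.88 for cholesterol synthesis, and that of ribosomal proteins, −0.28 here, turned to 0.05 with cyclic loess.

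Genes for plasma proteins made by hepatocytes fell. Of 33 measured, 24 fell and 1 rose (25 and 1 adjusted over the list alone), with a median log2 fold change of −0.81. SERPINA1, alpha-1 antitrypsin, fell from 1239 ± 166 to 397 ± 34.0 CPM (SD, n = 3 each). Plasminogen (PLG), ITIH2 and fetuin-A (AHSG) fell 3.62-fold, 2.82-fold and 3.18-fold. The list's camera adjusted p was 1.69e-08, and the adjusted p with an estimated correlation 0.142. Of 22 liver transcription factors, 11 fell and 1 rose (12 and 1 adjusted over the list alone), at a median of −0.34. HNF4A had a log2 fold change of −0.85 ± 0.10 (SE), FOXA2 of −1.11 ± 0.17 and PPARA of −0.66 ± 0.10. Their camera adjusted p was 0.0101 (adjusted p = 0.213 with an estimated correlation). It ranged from 0.00177 to 0.0566 over 15 other settings, the highest with cyclic loess, and 7 of these genes fell without knockout replicate 1, without knockout replicate 2 or with library size alone.

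Drug and bile acid metabolism genes moved both ways, 9 of 23 up and 5 down (9 and 5 adjusted over the list alone). Their median of 0.61 lay above most matched random lists (99.96th percentile) and fry called them higher (adjusted p = 0.000788), while camera did not (adjusted p = 0.272). That median was 0.38 without control replicate 2, 0.39 with offsets for GC content and length and 0.20 with cyclic loess. BAAT, which joins bile acids to amino acids, rose by 3.32 ± 0.16 (SE) on the log2 scale and the glutathione transferase GSTA2 rose 2.55-fold. GSTA2 shares sequence with its paralogs. The 5 falls were 3 without knockout replicate 1 or 2, with the replicate number as a block, and with upper-quartile scaling or library size alone. Of 18 markers of fetal liver and liver tumours, 5 rose and 10 fell (6 and 10 adjusted over the list alone; camera adjusted p = 0.0904). The growth factor IGF2 fell from 967 ± 275 to 262 ± 11.1 CPM and PROM1 rose from 251 ± 39.3 to 509 ± 9.90 CPM. DLK1 had 134 counts in the controls and 0 in the knockout, at least 50.5-fold lower against a floor of 3 counts over the group. With cyclic loess 6 genes of this list rose and 5 fell. The list passed downward with library size alone (0.0384) and with no filter on low counts (0.0363), in a camera range of 0.0363 to 0.736 over 15 other settings, and by fry (0.000788).

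Cholesterol synthesis genes fell nearly as a block. Of 26 measured, 21 fell and 1 rose (21 and 1 adjusted over the list alone), at a median of −0.88. Squalene epoxidase (SQLE) fell from 106 ± 11.5 to 30.4 ± 3.25 CPM (SD, n = 3 each), MSMO1 fell 2.81-fold and squalene synthase (FDFT1) 2.28-fold. Camera gave 1.16e-09 as the adjusted p, and an adjusted p of 0.0954 with an estimated correlation. In fatty acid and triglyceride synthesis, 16 of 25 genes fell and 2 rose (16 and 2 adjusted over the list alone), at a median of −0.52. The stearoyl-CoA desaturase SCD fell from 2407 ± 157 to 1000 ± 68.2 CPM. The desaturase FADS2, the lipid droplet protein PNPLA3 and the elongase ELOVL6 fell 3.13-fold, 3.71-fold and 2.57-fold. This list had a camera adjusted p of 1.03e-05 (adjusted p = 0.169 with an estimated correlation). Fatty acid oxidation did not pass (camera adjusted p = 0.263), with 4 of 23 genes up and 9 down (5 and 9 adjusted over the list alone). Its median of 0.024 turned to −0.22 without knockout replicate 1 and −0.14 without control replicate 3, so it has no stable sign. Library size alone gave 0.20, a move shared by all genes. Less the median of all genes, the list stood at −0.03 in both fits. Its mean was −0.10. CPT1A, which admits fatty acids to mitochondria, rose 2.09-fold. With library size alone 8 rose and 5 fell, with cyclic loess 7 and 7, and without knockout replicate 1 or 3 only 1 gene rose.

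Genes of glycolysis went both ways, with more falls than rises. Of 22 genes, 12 fell and 6 rose (13 and 6 adjusted over the list alone). Abundant members fell, GAPDH from 6718 ± 1018 to 2559 ± 172 CPM, LDHA from 1240 ± 89.4 to 436 ± 14.5 CPM and PKM from 1438 ± 122 to 722 ± 9.42 CPM (SD, n = 3 each). The glucose transporter SLC2A3 rose from 1.44 ± 0.361 to 22.2 ± 4.12 CPM. The list's median was −0.54 and its mean 0.04, opposite in sign. Its camera adjusted p of 0.0307 (adjusted p = 0.625 with an estimated correlation) passed in 8 of 15 other settings and ranged from 0.00669 to 0.257 there. It was 0.0932 without control replicate 1, 0.084 without control replicate 2 and 0.0515 without knockout replicate 1. It was 0.0528 with a filter of 1 CPM, 0.0507 without the added loci, 0.257 with cyclic loess, 0.0824 with offsets for GC content and length, and 0.0874 by fry. Hypoxia response genes did not pass (camera adjusted p = 0.272), with 6 of 23 up and 8 down (6 and 9 adjusted over the list alone). The lysyl oxidase LOX and the carbonic anhydrase CA12 fell 1.88-fold and 1.80-fold. With library size alone 6 rose and 4 fell, and without knockout replicate 2 the numbers were 6 and 6.

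Interferon response genes rose together. Of 34 measured, 25 rose and none fell (26 and none adjusted over the list alone). The median log2 fold change was 1.30, the same with BST2 at its bound. The list was fixed with 41 genes. OAS2, IFI44, IFI44L, XAF1, RSAD2, CMPK2 and EPSTI1 were not among the tested genes, so nothing is shown for them. Without control replicate 1, and with offsets for GC content and length, 1 member fell. The transcription factor IRF1 rose from 5.93 ± 1.24 to 32.9 ± 1.22 CPM (SD, n = 3 each), LGALS3BP from 0.892 ± 0.481 to 11.5 ± 0.904 CPM and PARP14 from 26.6 ± 3.50 to 75.7 ± 8.04 CPM. BST2, tetherin, had 0 counts in the controls and 1080 in the knockout, at least 318-fold higher against a floor of 3 counts over the group. Camera gave an adjusted p of 6.26e-08 (adjusted p = 0.0933 with an estimated correlation). Sensors of nucleic acids did not pass camera (adjusted p = 0.670) and were called higher by fry (adjusted p = 0.0305), with 3 of 15 up and 1 down (3 and 1 adjusted over the list alone). Falls numbered 3 without control replicate 1 and 4 with offsets for GC content and length. The RNA sensor IFIH1 rose from 0.515 ± 0.137 CPM by 2.95 ± 0.31 (SE) on the log2 scale, 2.35 with cyclic loess, and TRIM25 rose from 145 ± 8.09 to 217 ± 8.86 CPM. The median of this list was −0.0039, turning to 0.23 without control replicate 1, and its mean was 0.38. Library size alone gave a median of 0.18, a move shared by all genes. Less the median of all genes, the sensors stood at −0.06 in both fits.

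NF-kB and inflammatory genes had 13 rises and 3 falls among 25 (13 and 6 adjusted over the list alone) and a camera adjusted p of 0.0796. They passed upward with no filter on low counts (0.0482), without the added loci (0.0395) and with cyclic loess (0.0298), in a range of 0.0298 to 0.184 over 15 other settings, and by fry (0.00623). Rises and falls numbered 11 and 6 without control replicate 3 and 13 and 6 with offsets for GC content and length. BIRC3, an inhibitor of apoptosis, rose from 10.2 ± 2.34 to 38.9 ± 4.70 CPM and the chemokine CXCL6 rose 6.14-fold. Acute phase genes had 11 rises and 7 falls among 21 (11 and 9 adjusted over the list alone; camera adjusted p = 0.670; called higher by fry, adjusted p = 0.0471). C4BPB, a chain of the complement regulator C4b-binding protein, rose 9.67-fold, and STAT3 rose from 88.3 ± 5.99 to 267 ± 11.2 CPM.

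Genes of the amino acid response driven by ATF4 rose. Of 31 measured, 25 rose and none fell (26 and none adjusted over the list alone), at a median of 0.69. Asparagine synthetase (ASNS) rose from 83.3 ± 1.02 to 253 ± 2.68 CPM (SD, n = 3 each). VLDLR, the transcription factor ATF3 and the phosphatase regulator PPP1R15A rose 4.15-fold, 3.14-fold and 2.29-fold. The camera adjusted p was 1.80e-07, and the adjusted p with an estimated correlation 0.189. In the unfolded protein response, 9 of 22 genes fell and 3 rose (12 and 3 adjusted over the list alone), at a median of −0.27. SEC24D, a coat protein of vesicles leaving the endoplasmic reticulum, fell by 1.48 ± 0.12 (SE) on the log2 scale, MANF fell 1.62-fold, SYVN1 1.88-fold and DNAJB11 1.42-fold. The camera adjusted p of this list was 0.0176 (adjusted p = 0.213 with an estimated correlation), with a range of 0.00417 to 0.840 over 15 other settings, the highest with cyclic loess, and the list's median lay at the 25.2th percentile of expression-matched random lists. Rises and falls numbered 5 and 5 with library size alone, 4 and 4 with cyclic loess, 1 and 5 without knockout replicate 2, and 1 and 14 with offsets for GC content and length.

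Heat shock genes had 11 falls and no rise among 22 (12 and none adjusted over the list alone), at a median of −0.38. With library size alone or cyclic loess 2 members rose. STIP1 and FKBP4, which assist HSP90, fell 2.18-fold and 2.00-fold, HSPA8 1.68-fold and HSP90AB1 1.46-fold. HSP90AB1 was no longer called with cyclic loess (−0.18, adjusted p = 0.189). The camera adjusted p was 0.000124 (adjusted p = 0.0954 with an estimated correlation), and the median lay at the 4.09th percentile of matched random lists. NRF2 targets had 8 rises and 8 falls among 25 (8 and 8 adjusted over the list alone), with a camera adjusted p of 0.864. Their mean was 0.15 and their median −0.08, which turned to 0.21 with cyclic loess. Library size alone gave a median of 0.11, a move shared by all genes. Less the median of all genes, these targets stood at −0.13 in both fits. AKR1C3, which has close paralogs, rose 6.28-fold and thioredoxin reductase (TXNRD1) rose 2.17-fold. The 8 falls were 5 without knockout replicate 1, without knockout replicate 2 or with library size alone, and 4 with cyclic loess. Targets of p53 had 8 rises and 3 falls among 25 (8 and 4 adjusted over the list alone; camera adjusted p = 0.390). TP53INP1 rose 3.35-fold. PLK2 rose from 1.61 ± 0.997 to 11.2 ± 0.962 CPM, a log2 fold change of 2.77 that was 3.36 without control replicate 1. Apoptosis regulators had 12 rises and 2 falls among 30 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0861). PMAIP1, a pro-apoptotic BCL2-family protein, rose 3.11-fold, and BIRC3 is on this list too. Without knockout replicate 1, 6 of these genes rose and 0 fell, and with library size alone 18 and 0. The list passed upward without control replicate 1 (0.0437), without the added loci (0.0335) and with cyclic loess (0.0130), in a range of 0.0130 to 0.255 over 15 other settings, and by fry (0.0170).

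Other members of the hnRNP family fell with the target. Of 30 measured, HNRNPA2B1 left out, 19 fell and none rose (21 and 1 adjusted over the list alone), at a median of −0.42. HNRNPC fell from 973 ± 54.0 CPM (SD, n = 3) to 552 CPM, HNRNPL 1.77-fold and HNRNPAB 1.71-fold. For the family, the camera adjusted p was 4.91e-06 (adjusted p = 0.0954 with an estimated correlation). The median lay at the 4.05th percentile of matched random lists, and rises and falls numbered 3 and 11 with cyclic loess and 4 and 13 with library size alone. SR splicing factors and their kinases had 12 falls and 1 rise among 24 (12 and 1 adjusted over the list alone), at a median of −0.32. TRA2B fell 1.92-fold, CLK2 2.11-fold, SRSF10 1.71-fold and CLK3 1.56-fold. Their camera adjusted p was 0.00964 (adjusted p = 0.360 with an estimated correlation). It ranged from 0.00155 to 0.279 over 15 other settings, the highest with cyclic loess, and the median lay at the 8.36th percentile of matched random lists.

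Writers, erasers and readers of N6-methyladenosine had 6 falls and no rise among 19 (6 and none adjusted over the list alone), at a median of −0.24. METTL16, IGF2BP2, FTO and IGF2BP1 fell 1.53-fold, 1.65-fold, 1.46-fold and 1.35-fold. IGF2BP1 was no longer called with library size alone (adjusted p = 0.0694) or with cyclic loess (adjusted p = 0.278). The list had a camera adjusted p of 0.0307 (adjusted p = 0.189 with an estimated correlation), passed in 10 of 15 other settings with a range of 0.00831 to 0.557, and did not pass with upper-quartile scaling (0.0542), library size alone (0.0804), a filter of 1 CPM (0.0528), without the added loci (0.0786) or with cyclic loess. Its median lay at the 23.5th percentile of matched random lists. Rises and falls numbered 2 and 3 with library size alone, 2 and 4 with cyclic loess, and 0 and 11 with offsets for GC content and length. Genes of microRNA processing had 1 rise and 4 falls among 19 (1 and 3 adjusted over the list alone; camera adjusted p = 0.339), and 4 and 3 with library size alone. XPO5, the exporter of microRNA precursors, fell 1.53-fold and AGO4 rose 1.75-fold.

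Genes of the cell cycle fell. In DNA replication and S phase, 20 of 40 fell and 1 rose (20 and 1 adjusted over the list alone), at a median of −0.42. The helicase subunits MCM2, MCM3, MCM4 and MCM7 had log2 fold changes of −0.92 ± 0.11, −0.77 ± 0.09, −0.90 ± 0.10 and −0.95 ± 0.12 (SE). Camera gave an adjusted p of 1.80e-07 (adjusted p = 0.189 with an estimated correlation), and offsets for GC content and length gave 31 falls. In the mitosis list, 20 of 36 fell and 1 rose (20 and 1 adjusted over the list alone), at a median of −0.45. The kinase PLK1 fell from 181 ± 26.6 to 67.5 ± 3.59 CPM (SD, n = 3 each), AURKB fell 1.84-fold, CCNA2 1.83-fold and BUB1 1.75-fold. This list had a camera adjusted p of 6.13e-06 (adjusted p = 0.142 with an estimated correlation).

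Wnt target genes fell, 11 of 17 with 1 rise (14 and 1 adjusted over the list alone), at a median of −0.65. The receptor LGR5 fell from 73.3 ± 12.1 to 21.8 ± 1.04 CPM (SD, n = 3 each), the antagonist DKK1 2.20-fold and glutamine synthetase (GLUL) 2.02-fold. The receptor TNFRSF19 was the member that rose, 2.46-fold. Their camera adjusted p was 3.57e-05 (adjusted p = 0.184 with an estimated correlation). TGF-beta target genes rose, 12 of 23 with 1 fall (13 and 1 adjusted over the list alone), at a median of 0.63 that was 0.34 with offsets for GC content and length and 0.48 without control replicate 2. The matricellular protein CCN1 rose from 55.8 ± 8.87 to 179 ± 14.3 CPM, TGFBI rose 2.38-fold, and ANKRD1, among the largest rises, is on this list. BAMBI, a pseudoreceptor that dampens TGF-beta signalling, rose 1.99-fold. The TGF-beta list had a camera adjusted p of 0.000892 (adjusted p = 0.263 with an estimated correlation). Immediate early genes of growth factor signalling went both ways, 7 of 28 up and 11 down (8 and 12 adjusted over the list alone; camera adjusted p = 0.272), and 9 and 9 with library size alone. The phosphatase DUSP6 fell from 195 ± 6.74 to 57.4 ± 5.32 CPM and FOSL2 rose 2.73-fold.

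Mesenchymal and migration genes had 10 rises and 2 falls among 20 (10 and 2 adjusted over the list alone), at a median of 0.68. Of the 27 genes fixed for this list, SNAI2, ZEB2, TWIST1, TWIST2, MMP1, MMP2 and MMP9 were not among the tested genes. Vimentin (VIM) rose from 82.5 ± 14.2 to 176 ± 1.54 CPM (SD, n = 3 each) and SPARC from 0.323 ± 0.070 to 5.37 ± 1.55 CPM. The log2 fold change of SPARC, 4.05, was 3.29 with cyclic loess, and its level was highest in knockout replicate 2 (6.98 CPM), the library with most collagen reads. Fibroblast markers, given with the other cell types, rose alongside this list. The metalloprotease MMP7 had 4 counts over the controls and 298 over the knockout libraries. As a list these genes had a camera adjusted p of 0.0171 (adjusted p = 0.189 with an estimated correlation). Epithelial junction genes had 12 rises and 8 falls among 29 (13 and 8 adjusted over the list alone; camera adjusted p = 0.390). They passed upward with cyclic loess (0.0379; range 0.0379 to 0.564 over 15 other settings) and by fry (0.000788). The gap junction protein GJB1 fell 2.91-fold and the claudin CLDN7 rose 5.71-fold.

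Ribosomal protein genes had 17 falls and no rise among 47 (17 and none adjusted over the list alone), at a median of −0.28 that turned to 0.05 with cyclic loess. RPS15, RPL6 and RPL35 fell 2.09-fold, 1.46-fold and 1.85-fold, and RPL6 lost its call with cyclic loess (adjusted p = 0.0963). Their camera adjusted p was 0.000566 (adjusted p = 0.607 with an estimated correlation), with a range of 3.37e-07 to 0.840 over 15 other settings, and 0.147 by fry. The falls numbered 30 without control replicate 3, rises and falls 4 and 18 without control replicate 1 and 2 and 5 with cyclic loess, and the median lay at the 46.9th percentile of matched random lists. Reads of these genes can be shared with processed pseudogenes. Nuclear genes of oxidative phosphorylation had 13 falls and no rise among 35 (13 and none adjusted over the list alone), at a median of −0.24. SDHA and SDHB of complex II had log2 fold changes of −0.68 ± 0.11 and −0.67 ± 0.11 (SE), CYC1 of complex III −0.68 ± 0.13 and ATP5F1B of the ATP synthase −0.66, the last not called with cyclic loess (adjusted p = 0.114). The list's camera adjusted p was 0.000249 (adjusted p = 0.564 with an estimated correlation). It ranged from 1.49e-07 to 0.113 over 15 other settings, the highest with cyclic loess, was 0.0881 by fry, and the median lay at the 19.2th percentile of matched random lists. A member rose without control replicate 1. The falls numbered 24 without control replicate 3, 8 without knockout replicate 1, 8 without knockout replicate 2, 8 with cyclic loess, 7 with library size alone and 22 with offsets for GC content and length.

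Among the lists that track RNA quality, 6 of 13 mitochondrial transcripts fell (7 adjusted over the list alone), at a median of −0.68. MT-ND3 fell 1.77-fold. MT-ND1, MT-ND2 and MT-ATP6 had log2 fold changes of −0.78 ± 0.24, −0.99 ± 0.31 and −0.72 ± 0.23 (SE), and their knockout values overlapped the controls. The falls numbered 12 without control replicate 1 and 1 when any other single library was left out, and the median was −0.29 without control replicate 3, the library with 4.70% mitochondrial counts. Camera gave an adjusted p of 0.0139 (adjusted p = 0.625 with an estimated correlation), which was 0.106 without control replicate 3, 0.411 with cyclic loess, 0.113 with offsets for GC content and length and 0.197 by fry, and ranged from 0.000162 to 0.411 over 15 other settings. The list of histone and non-polyadenylated transcripts had 1 rise and 1 fall among 7, all of them histone genes (1 and 1 adjusted over the list alone, camera adjusted p = 0.473). Its other RNAs, RMRP, RPPH1, RN7SK, RN7SL1, RN7SL2, MALAT1 and NEAT1, were not among the tested genes, so nothing is shown for them.

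Markers of other cell types were measured as well. Of 7 fibroblast and stellate cell genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0796), at a median of 2.00, above all matched random lists. The list passed camera with the replicate number as a block (0.0321), without knockout replicate 3 (0.0346) and with no filter on low counts (0.0247), in a range of 0.0247 to 0.191 over 15 other settings, and by fry (0.00502). The fall was that of PDGFRA, and fibrillin (FBN1) rose 3.43-fold. Knockout replicate 2 stood apart for collagens, with 4.70 CPM of COL1A1, 3.56 CPM of COL1A2 and 7.47 CPM of COL3A1, against at most 0.756 CPM of each in the other 5 libraries. Without that library 3 of the list's genes rose, and with no filter on low counts 10 did. Of 9 leukocyte genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.670; 3 and 5 with cyclic loess), with a median of −0.62 and a mean of 0.18. The actin-bundling protein LCP1 rose from 16.2 ± 0.628 to 51.9 ± 1.39 CPM and lysozyme (LYZ) fell from 311 ± 52.5 to 86.1 ± 7.48 CPM (SD, n = 3 each), so both were expressed in the controls. Of 12 cholangiocyte genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.390; called higher by fry, adjusted p = 0.0208). SOX9 fell 2.21-fold and TFF3 rose 4.44-fold. Of 4 endothelial genes, too few for a list test, 1 fell and none rose (1 and none adjusted over the list alone), PECAM1, which was named after its value was seen, from 59.9 to 33.2 CPM.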

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

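Leaving out the added loci, cyclic loess with limma-trend and the offsets for GC content and length were chosen after seeing the data; the other settings were planned. HNRNPA2B1 kept its direction and its call in the 17 alternatives that gave it a value, at log2 fold changes of −2.61 to −2.10. The count of 6548 called genes became 3984 at an adjusted p below 0.01, by construction. It ran from 4416 without knockout replicate 1 to 6895 without control replicate 3 when single libraries were left out, and the count changed 2-fold from 1883 to 2466. DESeq2 called 7068 genes, with 6 adjusted p-values not given, limma-voom 6774, the fit without the added loci 5692, cyclic loess 5804 and the offsets 8032. The number of called lists fell from 20 to 0 with an estimated correlation, was 25 with fry (12 up, 13 down) and 15 with cyclic loess (7 up, 8 down), and ran from 19 to 21 when single libraries were left out.

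Of the results for 132 named genes other than the target over the alternatives, 2215 stayed on their side of the threshold with their direction, 29 lost the call and 0 reversed. The losses lay in 7 genes, MT-ND1, MT-ND2, MT-ATP6, IGF2BP1, HSP90AB1, RPL6 and ATP5F1B. Of the results for lists, 564 stayed, 43 lost the call, 21 gained it and 1 reversed. The reversed one was the ribosomal protein list, whose direction turned with cyclic loess at an adjusted p of 0.840 and whose adjusted p otherwise was as low as 3.37e-07; the cause was not tested.

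With the replicate number as a block, 5739 genes were called and 85.8% of the calls of the fit without it were shared; 2149 genes changed 2-fold, 21 lists passed and HNRNPA2B1 had −2.39. The numbers do not pair the libraries. Deviations of same-numbered libraries from their group means correlated at 0.04, −0.07 and −0.07 across genes. The simulated data gave calls for 24% of genes changed 1.5-fold. They gave 143 calls in all, against 6548 in the real data, and with fewer calls the Benjamini-Hochberg cutoff is stricter. The 24% therefore does not measure the share of such changes called here. FTO, 1.46-fold lower (edgeR adjusted p = 0.00495), was among the smaller changes that were called. Small changes can still go uncalled, and their share was not measured.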

Other observations

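The 21 gene families in this paragraph and the next were chosen after seeing the data. Genes of class I antigen presentation were higher in the knockout. Of 18 measured, 13 rose and 2 fell (14 and 2 adjusted over the list alone), at a median log2 fold change of 0.91. The peptide transporter TAP1 rose from 1.88 to 23.8 CPM (log2 fold change 3.66 ± 0.18 SE), the immunoproteasome subunit PSMB9 from 0.129 to 4.75 CPM and beta-2-microglobulin (B2M) from 227 to 427 CPM, means of 3 libraries. NLRC5, a transcriptional activator of these genes, rose by 3.16 ± 0.36 on the log2 scale. The camera adjusted p over the 21 families was 0.00061, and the adjusted p with an estimated correlation 0.153. Of 6 guanylate-binding protein genes, which interferon induces, 5 rose and none fell (5 and none adjusted over the list alone; camera adjusted p = 0.00061, adjusted p = 0.153 with an estimated correlation). GBP3 rose by 3.88 ± 0.24 (SE), and GBP5 had 0 counts in the controls and 146 in the knockout, at least 43.0-fold higher against a floor of 3 counts over the group.

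Of 11 UDP-glucuronosyltransferase genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.003, adjusted p = 0.153 with an estimated correlation). UGT2B7 rose from 3.98 to 20.1 CPM and UGT1A1 from 28.8 to 75.1 CPM, although reads are readily shared within this family. Laminin chains had 6 rises and 1 fall among 9 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00763, adjusted p = 0.153 with an estimated correlation), with LAMB3 up from 5.33 to 19.9 CPM and LAMA5 from 167 to 314 CPM. Integrins had 12 rises and 1 fall among 23 (12 and 1 adjusted over the list alone; camera adjusted p = 0.0426, adjusted p = 0.190 with an estimated correlation), with ITGAV up from 315 to 650 CPM. Metallothioneins had 5 falls and no rise among 7 (6 and none adjusted over the list alone; camera adjusted p = 0.003, adjusted p = 0.219 with an estimated correlation). Mitochondrial ribosomal proteins had 36 falls and no rise among 78 (38 and none adjusted over the list alone; camera adjusted p = 8.88e-07, adjusted p = 0.323 with an estimated correlation), with MRPS15 down from 115 to 57.2 CPM. Of 22 spliceosome Sm and LSm proteins, 11 fell and none rose (11 and none adjusted over the list alone; camera adjusted p = 0.00163, adjusted p = 0.183 with an estimated correlation). Camera also passed translation initiation factors (22 falls and 6 rises among 53, 22 and 6 adjusted over the list alone), high mobility group proteins (6 falls among 9, 7 adjusted over the list alone) and chaperonin subunits (5 falls among 9, 7 and 1 rise adjusted over the list alone). Their camera adjusted p was 0.00326, 0.00326 and 0.0183 (adjusted p = 0.153, 0.219 and 0.338 with an estimated correlation), but their medians lay at the 22.1th, 11.4th and 25.3th percentiles of matched random lists, within the range of genes of like abundance. The other 10 families did not pass or had too few members.

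In the paragraphs that follow, the tests of background reads, of scaling and of leukocytes or fibroblasts were chosen only after the results were seen. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05, and for each of the 3 counts here 1 split, the real one, gave a value as large. The real split called 6548 genes and the highest of the others 1. For 2-fold changes the numbers were 2273 and 1. For gene lists they were 20 and 18. Each of the other splits mixes control and knockout libraries on both sides, so part of the group difference remains in it. Their counts therefore do not show what arises without a group difference. No list passed camera with an estimated correlation (lowest adjusted p 0.0933). As their calls hang on the preset correlation, the lists are weaker evidence than the calls of single genes.

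More annotated genes rose than fell 2-fold. Background reads from genomic DNA were tested through 544 genes of families silent in liver, such as olfactory receptors. Only 55 to 66 of them held a count in a control library and 79 to 81 in a knockout library. Their counts were thus uneven and are not a clean measure of genomic DNA. Summed over these families, counts per kb were 1.72 times higher in the knockout libraries. That extra density, multiplied by transcript length, reached the rise in 0% of the 1184 risen genes with a known length and gave a median of 1.07% of it. For these annotated genes, this argues against a uniform background of genomic DNA as the source of the rises. The loci added by the authors' pipeline were not covered. They took 2.00 ± 0.127% of counts in the controls and 3.00 ± 0.620% in the knockout (SD, n = 3 each), so background in them stays open. Unspliced RNA was not tested and stays open, since genes that are not transcribed carry none. A wrong scaling factor cannot be told apart from a true excess. Rises made up at least 68.9% of the annotated 2-fold calls under each planned scaling, but of these only DESeq2's size factors lowered the median of all genes, from 0.05 to 0.03, so the test had little reach. A single factor per library moves all genes alike and leaves the gap between the medians of rare genes (0.67) and abundant genes (−0.21) as it is. A shift that follows abundance stays open. Rises were 55.8% of the annotated 2-fold calls with cyclic loess, 60.3% with offsets for GC content and length and 64.4% without control replicate 1. Cyclic loess came with another test, limma-trend, and with a prior count of 2, and the offsets moved the median of all genes to −0.06. These shares therefore do not measure such a shift alone. A biological effect of the knockout, or a difference between the cell populations the guides were put into, also stays open and was not tested.

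The hnRNP family fell beside its targeted member. GC content and transcript length are argued against as the whole cause. After the offsets for both the family's median was −0.51, against −0.06 over all genes. Before the offsets these medians were −0.42 and 0.05. The move from −0.42 to −0.51 thus mixes a shift of all genes with any effect of GC content and length. A shift shared by abundant genes cannot be told apart from a fall of this family, because its median lay at the 4.05th percentile of expression-matched random lists, between the bounds set for either reading. With cyclic loess, which removes such a shift, the median was −0.22, and the list still passed at a camera adjusted p of 0.0379 (range over 15 settings 1.17e-07 to 0.0379).

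Interferon response genes rose by a median of 1.30. GC content and transcript length are argued against, since the median was 1.25 after the offsets. Leukocytes or fibroblasts mixed into the knockout cultures were tested through 7 of their transcripts that were below 1 CPM in the controls. These rose by 10.2 CPM together, 2.58% of the 393 CPM by which the interferon list rose. Transcripts at 1 CPM or more in the controls were left out, of which LCP1 rose by 35.7 CPM and CORO1A and LYZ fell. How much interferon transcript such cells would bring per marker was not measured, so this share cannot exclude them as a source. LUM, a fibroblast marker, was at 5.04, 5.22 and 3.94 CPM in knockout replicates 1, 2 and 3 against at most 1.18 CPM in the controls. Collagens were highest in knockout replicate 2, as were DCN (1.03 CPM), PTPRC (0.513 CPM) and TYROBP (0.171 CPM), these 3 at few counts. A share of such cells, or expression of these genes by the Huh7 cells, therefore stays open. It also stays open whether the rise may follow from loss of HNRNPA2B1, from the guide or from a difference between clones, none of which this design separates.

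HMGA2 and, chosen after their values were seen, LIN28B (−1.92) and MYCN (−1.91) fell together. As all are known targets of the let-7 microRNA family, higher let-7 activity was a candidate explanation. Over 13115 genes with a 3′ UTR, these left out, the 1236 with the let-7 seed match CTACCTC had an adjusted log2 fold change lower by a difference of −0.033, at the 8.71th percentile of 13783 7-base words. The other let-7 match, TACCTCA, had a difference of 0.016 (z = 0.69), at the 75.8th percentile. CTACCTC lay between the bounds set beforehand and TACCTCA on the side set as against let-7, neither by a difference beyond its spread. Neither match was within the lowest 5% that higher let-7 activity would need, and the explanation stays open.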
